A study of Mus musculus with 26 samples.

How the data were processed

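CTCF and H3K27ac were measured by ChIP-seq in mouse iPS cells from 4 founder cell types at P3 and P20. The iPS cells grew on mitomycin-C-treated MEF feeder cells, per the labels' protocols. The antibodies came from Millipore (CTCF) and Abcam (H3K27ac). Samples were grouped by antibody, founder and passage as the labels give them, which made 8 CTCF groups of 2 replicates and 8 H3K27ac groups of 1 library. A further 2 whole-cell extract libraries are labelled in the series, 1 per passage, and were not analysed here.

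The authors aligned reads with BWA to mm9 and called peaks with MACS2, per the submitters' processing notes. Versions, parameters, duplicate handling and the control library behind each list are not given in the sources used here. If each passage was called against its own whole-cell extract, a difference between the controls would go with passage. There was 1 list per library, so replicates were not pooled. In each deposited list the authors give a fold enrichment (ratio) per peak over the caller's local background, the −log10 p and the −log10 q of the peak, and the offset of its summit. The lowest −log10 q in any list was 1.30, as a threshold of q = 0.05 would leave. These are the authors' values for the peak within its own list, and they were used only to describe, rank or filter peaks within a list. No read counts come with the lists, so depth is unknown, and a library with more reads or better enrichment yields more and weaker peaks. Median fold enrichment ran from 9.09 to 12.3 in the CTCF lists and from 4.40 to 5.02 in the H3K27ac lists. No pair of CTCF lists was identical.

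Peaks of all lists of one antibody that shared at least 1 base were merged into a region, and each library was scored for the presence of a peak. Similarity was the Jaccard index over regions for CTCF and over covered bases for H3K27ac. All analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Similarities, peak numbers and shares were compared with exact permutation tests. Passages were exchanged within founders (16 arrangements for H3K27ac), founder labels of the P20 lists were permuted (24 arrangements), and the 8 libraries of a passage were partitioned into pairs in all possible ways. Presence per region was tested with Fisher's exact test and Benjamini-Hochberg adjustment at 0.05. Regions specific to a founder were those with a peak in all its libraries of a passage and in none of the other founders. Shares carry exact (Clopper-Pearson) 95% intervals.

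The comparisons, their tests and their alternatives were fixed before the data were examined, except the change of founder separation between passages, the chromosome offsets, the tests of passage effects between founders over 84 combinations, the simulated sets without a founder effect, the counts at an unadjusted p and of regions held or lacked by one founder at equal list lengths, the list lengths of other splits, the densest windows of H3K27ac regions, the H3K27ac regions read in a founder left out and the runs that left out 3 CTCF lists together. Further exceptions were the backward reading of P20 founder-specific regions at P3 and the search for libraries far from the others of their passage. The correlations of replicate numbers and the chromosomes of regions held or lacked by one founder were not fixed beforehand either. Chromosome offsets were computed over regions that all 16 libraries hold. Percentiles of fold enrichment were taken anew over those regions in each library. The median of the region over libraries and the library's median over autosomes were then subtracted, and the median per chromosome was taken.

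Regions are named by position. The rule, fixed beforehand, takes up to 10 regions per comparison and direction on assembled chromosomes. They must pass the test or, without a test, have a peak in all libraries of one side and none of the other, ordered by their lowest within-list percentile of fold enrichment. Of the founder-specific regions the text prints the leading ones. The annotation used here is of another build than mm9, so no gene was assigned to a peak, and the planned count of H3K27ac peaks at marker gene lists was not run. Base composition and motifs were not analysed here.

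The code was tested on simulated presence data drawn from the real region frequencies and list lengths. With 3000 of 126905 regions made specific to NSC, the Fisher test called 3018 regions and recovered all 3000 (100%). With 200 such regions it recovered 0, and with none it called 0. The planted regions had a peak in all NSC libraries and no other, so these outcomes follow from the 1395 needed for a call. Recovery of partial differences in presence was not simulated. The alternatives tried were peaks with −log10 q of at least 10, lists cut to the length of the shortest (55613 peaks for CTCF, 56871 for H3K27ac), regions built from summits within 200 bp, H3K27ac peaks within 1 kb joined, autosomes only, each CTCF library or each founder left out, and the replicate number as a block.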

Results

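The data were lists of ChIP-seq peaks from mouse induced pluripotent stem (iPS) cells derived from 4 founder cell types. The founders were bone marrow macrophages, mouse embryonic fibroblasts (MEF), neural stem cells (NSC) and bone marrow pre-B cells. Reprogramming was driven by doxycycline for 15 days, colonies were picked at day 20, and the lines were profiled early, after 3 passages (P3), and late, after 20 passages (P20). CTCF, a zinc-finger protein that binds insulators and anchors chromatin loops, was profiled in 16 libraries, with 2 replicates of each founder and passage. H3K27ac, a histone mark of active promoters and enhancers, was profiled in 8 libraries, with 1 library of each founder and passage. The labels do not say whether the 2 CTCF replicates are separate iPS lines, so the p-values measure only the spread between these libraries, which may be technical. No read totals come with the peak lists, so the depth of each library is unknown, and the number of peaks moves with it. All positions are in mm9, counted from 1.

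The first comparison asked whether early and late iPS cells differed in the number of CTCF sites. NSC-derived cells at P3 had the most CTCF peaks, 100118 ± 13748 (SD, n = 2). Pre-B-derived cells at P3 followed with 86053 ± 2298 (SD, n = 2), then MEF-derived cells with 70430 ± 1807 and macrophage-derived cells with 62898 ± 2579. At P20 the means were 79438 ± 483 for NSC, 76320 ± 20867 for pre-B, 69466 ± 10208 for MEF and 63168 ± 10684 for macrophage (SD, n = 2 each). Over the 8 libraries of each passage the mean was 79874 ± 16279 at P3 and 72098 ± 11776 at P20. The difference did not pass a two-sided exact permutation test over all exchanges of passages within founders (p = 0.168). It passed the same exact test without replicate 2 of pre-B P20 (a difference of -10488 peaks, p = 0.0494), and shrank to -3496 without replicate 2 of NSC P3 (p = 0.511) and to -5422 without replicate 1 of macrophage P20 (p = 0.381).

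**Figure D1:**
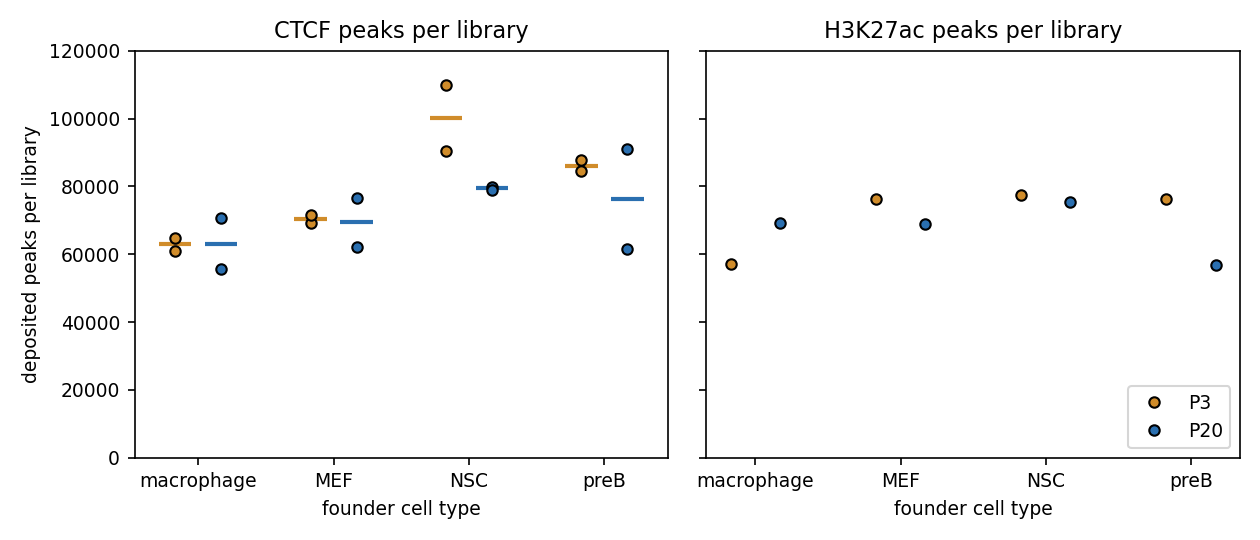
Number of deposited peaks per library for CTCF (left) and H3K27ac (right), by founder and passage. Points are libraries and bars are means of 2 CTCF replicates. NSC P3 holds the longest CTCF list, with 109839 peaks, and macrophage P20 the shortest, with 55613.

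The 16 CTCF lists merged into 126905 regions. A core of 43793 regions (34.5%) had a peak in all 16 libraries and held 60.5% of all CTCF peaks, while 23520 regions (18.5%) had a peak in 1 library. Whether founders could be told apart by their CTCF sites was tested on the Jaccard index, the share of the regions of 2 lists that both lists hold. At P3, replicates of one founder shared more sites (mean index 0.768 ± 0.0397, SD over 4 pairs) than libraries of different founders did (0.692 ± 0.0817, SD over 24 pairs). That difference of 0.0764 passed a one-sided exact permutation test over all partitions of the libraries into pairs (p = 0.019). At P20 the replicate pairs had a mean of 0.740 ± 0.0753 and the pairs of different founders 0.731 ± 0.0575, a difference of 0.00898 that did not pass the same exact test (p = 0.371). The change of the difference from P3 to P20, -0.0674, did not pass its own two-sided exact permutation test (p = 0.0571). Both depended on single libraries. The P20 difference turned negative without replicate 1 (-0.0273) or 2 (-0.0257) of NSC P20, fell to 0.0021 without replicate 1 of macrophage P20, and rose to 0.0306 without replicate 1 of MEF P20 and to 0.0491 and 0.0211 without replicates 1 and 2 of pre-B P20, in turn. The change from P3 passed without replicate 1 or 2 of NSC P20 (-0.104 and -0.102), replicate 2 of macrophage P3 (-0.0922) or replicate 1 of macrophage P20 (-0.0743), and shrank to -0.0273 without replicate 1 of pre-B P20.

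The P3 separation was smaller at equal list lengths. With all lists cut to the 55613 strongest peaks, which removes differences in list length and weak peaks together, the P3 difference was 0.0195 (p = 0.019, exact permutation test), and the change to P20 was -0.00518 (p = 0.696). With peaks at −log10 q of at least 10 it was 0.0718 (p = 0.0286, exact permutation test). In 100 simulated sets with the real list lengths and no founder effect, the mean P3 difference was 0.0117 (highest 0.0134), and the same permutation test passed in all 100, so its p-value alone does not separate founder from list length. The separation also missed the threshold without replicate 2 of NSC P3 (0.058, p = 0.0762, exact permutation test) and without replicate 2 of pre-B P3 (0.073, p = 0.0762).

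**Figure D2:**
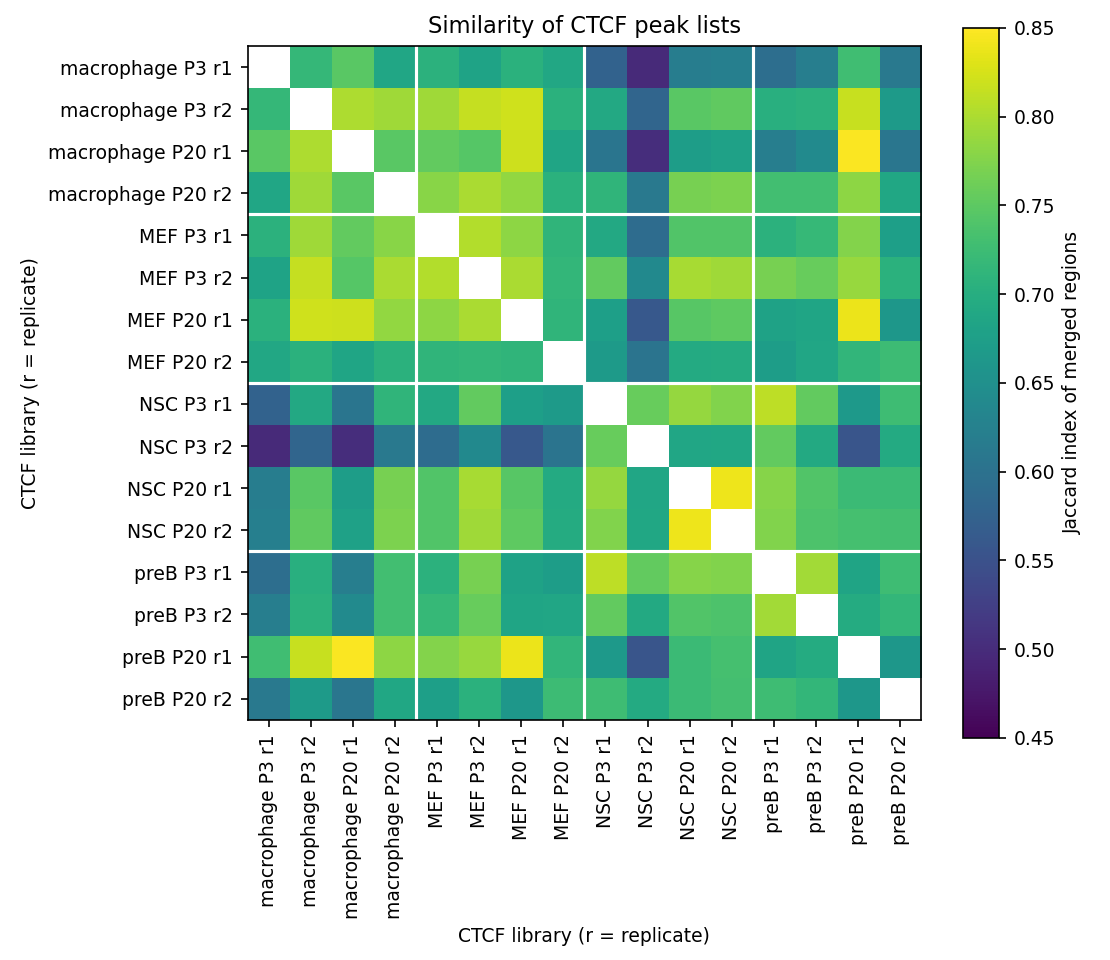
Jaccard index between each pair of the 16 CTCF lists, over merged regions, with libraries ordered by founder on both axes and white lines between founders. The replicates of NSC P20 are at 0.840, and the lowest index, 0.498, lies between macrophage P3 replicate 1 and NSC P3 replicate 2.

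Late cells of different founders were not measurably closer to one another than early cells. The mean index between founders was 0.731 at P20 and 0.692 at P3, a difference of 0.0392 (two-sided exact permutation test within founders, p = 0.375), and 0.00442 at equal list lengths (p = 0.889). It shrank to 0.0128 without replicate 1 of macrophage P3, 0.0172 without replicate 2 of NSC P3 and 0.0253 without replicate 1 of pre-B P20. P3 and P20 libraries of the same founder had a mean index of 0.737, against 0.701 for different founders. This difference of 0.036 gave a one-sided exact permutation p of 0.0417, the smallest that the 24 arrangements of founder labels can give. In the simulated sets without a founder effect this difference was 0.00508 on average (highest 0.00582) and passed the test in 96 of 100, so its p-value too does not separate founder from list length. It was 0.0404 with peaks at −log10 q of at least 10 (p = 0.0417, exact permutation test) and 0.00306 at equal list lengths (p = 0.333), and it missed the threshold without replicate 1 of macrophage P20 (0.0215), replicate 1 of pre-B P20 (0.0451) or replicate 2 of pre-B P20 (0.0268). MEF P3 lists resembled macrophage P20 lists (0.769) and NSC P20 lists (0.769) slightly more than MEF P20 lists (0.752), and pre-B P3 lists were closer to NSC P20 (0.758) than to pre-B P20 (0.705).

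No CTCF region was assigned to a passage or to a founder after adjustment. Fisher's exact test on peak presence with Benjamini-Hochberg adjustment over 126905 regions called 0 regions between P3 and P20 (1155 at an unadjusted p under 0.05, of which 1117 were more frequent at P3). It called 0 for each founder against the others, with unadjusted counts of 7060 for NSC, 2103 for macrophage, 1090 for pre-B and 327 for MEF. All 7060 NSC regions were more frequent in NSC, while 2071 of the 2103 macrophage regions were less frequent in macrophage-derived cells. The imbalance between passages nearly ended and the macrophage direction turned at equal list lengths, where 724 regions had an unadjusted p under 0.05 between passages, 383 more frequent at P3 and 341 at P20, and 494 for macrophage, 301 of them more frequent in macrophage-derived cells and 193 less. The MEF direction turned as well, from 62 more and 265 less frequent to 292 and 123, and for NSC 595 of 733 were more frequent. This test has little reach, since at its smallest p 395 regions split perfectly by passage, or 1395 split perfectly by a founder, would be needed for a call.

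Some regions nonetheless had a peak in all libraries of one side and none of the other. They are named here after their values were seen, since none passed the test. One region, chromosome 9 at 97034768 to 97035123, had a peak in all 8 P3 and no P20 library, with a lowest within-list percentile of fold enrichment of 1.94. At equal list lengths 2 regions parted the passages in this direction and 2 in the other. NSC-derived cells had 171 regions found in all 4 of their libraries and none of the other 12, led by chromosome 17 at 66529387 to 66529685, chromosome 10 at 91876650 to 91876959 and chromosome 18 at 34637923 to 34638218. These were weak peaks, the strongest with a lowest percentile of 26.9, and at equal list lengths 9 such regions were counted. Macrophage-derived cells lacked 47 regions that all 12 other libraries held, 7 at equal list lengths. The strongest lay on chromosome 10 at 22199475 to 22200268 (lowest percentile 64.3) and on chromosome 13 at 64008560 to 64009391 (52.4), and 8 of the 47 lay on chromosome 13, which holds 3.88% of all regions. MEF-derived cells lacked 5 such regions, 2 of them on chromosome Y (2363648 to 2364046 and 2420633 to 2421237), 2 on chromosome 3 (83798075 to 83798507 and 87386193 to 87387089) and 1 on chromosome 13 (89474109 to 89474469). They alone held chromosome 3 at 79058071 to 79058391. With all peaks no region was held or lacked by pre-B-derived cells alone. At equal list lengths 6 regions were held by pre-B-derived cells alone, 6 by macrophage and 5 by MEF, and 1 was lacked by pre-B, 1 by NSC and 5 by MEF.

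The fate of early founder-specific CTCF sites was then followed to P20. Regions with a peak in both P3 libraries of one founder and none of the other 6 numbered 3706 for NSC, 430 for pre-B, 20 for macrophage and 16 for MEF. By P20, 37.5% of the NSC regions (exact 95% binomial interval 35.9 to 39.0%) had a peak in an NSC library, against a mean of 22.6% in the other founders. For pre-B the share was 27.9% (23.7 to 32.4%) against 14.7%, for macrophage 55.0% (31.5 to 76.9%) against 40.0%, and for MEF 31.3% (5 of 16 regions, with an upper bound of 58.7%) against 20.8%. All intervals of this kind cover counting error only. The mean excess of the same founder was 13.4 percentage points, higher than the mean of the others in 4 of 4 founders, with a one-sided exact permutation p of 0.0833 over 24 arrangements (smallest possible 0.0417). Single founders did not all follow, since the MEF regions had a peak in pre-B P20 more often (43.8%) than in MEF P20, and the macrophage regions as often (55.0%). Read backwards, P20 founder-specific regions were found at P3 in the same founder more often than in the others for NSC (by 50.5 points, 2038 regions) and pre-B (27.8 points, 187 regions), and less often for MEF (-25.3 points, 29 regions) and macrophage (-16.7 points, 2 regions). NSC and pre-B also had the longest P3 lists, and replicates 1 and 2 of NSC P3 held 68.6% and 83.1% of all CTCF regions. The backward reading was not repeated at equal list lengths, so it does not separate founder from list length. The excess at P20 passed the exact test with peaks at −log10 q of at least 10 (15.9 points, p = 0.0417) and shrank to 2.01 points at equal list lengths (p = 0.333). It was 4.63 points without replicate 2 of NSC P3, 5.94 without replicate 2 of pre-B P3, 6.22 without replicate 2 of macrophage P20 and 6.35 without replicate 2 of macrophage P3.

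The founder-specific CTCF sites were mostly weak peaks, with a median within-list percentile of fold enrichment of 10.9 for NSC, 6.66 for pre-B, 11.2 for macrophage and 9.30 for MEF. The strongest macrophage region, chromosome 15 at 96483398 to 96483824, had a peak in both macrophage P20 libraries. The strongest NSC region, chromosome 3 at 53409324 to 53409625, had a peak in 1 of 2 NSC P20 libraries. The strongest pre-B region, chromosome 5 at 8423567 to 8423868, had no peak in any P20 library, and neither did the strongest MEF region, chromosome X at 6679493 to 6679745. Of the 16 MEF regions, 9 lay on chromosome X.

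**Figure D3:**
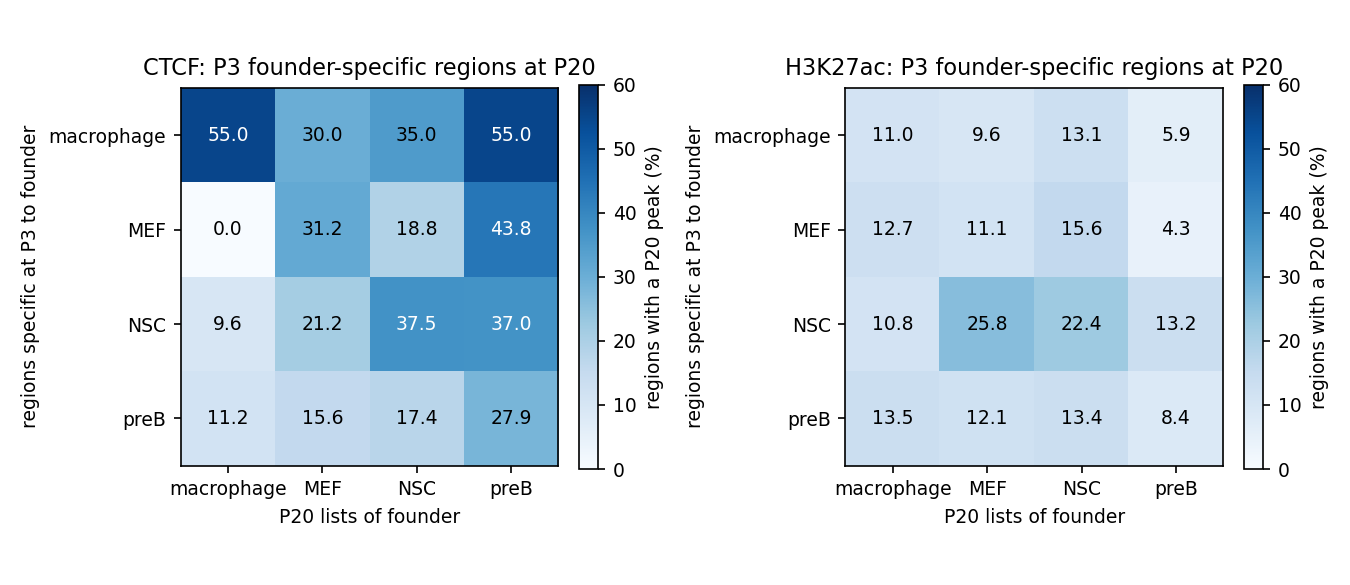
Share of P3 founder-specific regions (rows, by founder) with a peak at P20 in the lists of each founder (columns), in percent, for CTCF (left) and H3K27ac (right). For CTCF the same-founder share of NSC is 37.5%, close to 37.0% in pre-B P20, and for H3K27ac NSC regions were found in MEF P20 (25.8%) more than in NSC P20 (22.4%).

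H3K27ac was compared in the same way with 1 library per group, so founders served as the replicates. The lists held 57032 peaks in macrophage P3, 76415 in MEF P3, 77373 in NSC P3 and 76341 in pre-B P3, and 69333, 68829, 75398 and 56871 in the same founders at P20. The mean number was 71790 ± 9850 at P3 and 67608 ± 7755 at P20 (SD, n = 4, two-sided exact sign-flip permutation p = 0.625). Peaks covered 54.9 ± 10.9 Mb at P3 and 50.2 ± 7.23 Mb at P20 (SD, n = 4, exact permutation p = 0.75). With 16 arrangements of the labels, these tests cannot reach a p of 0.05. The direction rested on pre-B, without which P20 lists held 913 more peaks and 0.773 Mb more on average.

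A minority of the H3K27ac regions was common to all iPS cells. Of 117957 merged regions, 22089 (18.7%) had a peak in all 8 libraries and 44297 (37.6%) in 1. The mean Jaccard index over bases between founders was 0.551 at P20 and 0.532 at P3, a difference of 0.0182 (exact permutation p = 0.75, with 16 arrangements) that turned to -0.0123 without macrophage. P3 and P20 lists of the same founder had a mean index of 0.529, equal to 0.529 for different founders (difference 2.98e-05, one-sided exact permutation p = 0.458). NSC P3 was most similar to MEF P20 (0.617), ahead of NSC P20 (0.563).

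Between passages, 232 H3K27ac regions had a peak in all 4 P3 libraries and no P20 library, and 64 had a peak in all 4 P20 libraries and no P3 library. The P3-only regions with the highest lowest percentile lay on chromosome 9 at 107198849 to 107199503 (62.6), chromosome 1 at 21069552 to 21069892 (61.1), chromosome 16 at 78265785 to 78266564 (61.0), chromosome 14 at 55495164 to 55495565 (59.9) and chromosome 10 at 57718190 to 57718642 (59.0). They were followed by chromosome 5 at 72950151 to 72950894, chromosome 6 at 108615793 to 108616531, chromosome 17 at 25960568 to 25961521, and chromosome 5 at 125956217 to 125956732 and at 115157747 to 115158156. The P20-only regions were led by chromosome 11 at 116360080 to 116360536 (62.3), chromosome X at 84483525 to 84483933 (50.3), chromosome 10 at 98931234 to 98931725 (48.9), chromosome 6 at 140764382 to 140764852 (47.6) and chromosome 11 at 120694046 to 120694462 (40.7). They were followed by chromosome 17 at 29322060 to 29323154, chromosome 18 at 66224850 to 66225456, chromosome 11 at 9883308 to 9883847, chromosome 16 at 21175074 to 21175449 and chromosome 6 at 29548489 to 29549315. The sum of 296 regions was not unusual among the 35 splits of the 8 libraries into 4 and 4, of which 9 gave as many, the real one included. Both counts fell by more than 1.5 times at −log10 q of at least 10.

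Early founder-specific acetylation was mostly not found again at P20. These regions rest on 1 library each, without replicates. They were mostly weak peaks, with median within-list percentiles of fold enrichment from 22.1 for MEF to 25.9 for pre-B, so low recovery does not by itself show a loss. Regions with a peak in 1 P3 library and none of the other 3 numbered 4333 for macrophage, 10032 for MEF, 11256 for NSC and 13360 for pre-B. In the P20 list of the same founder, 475 of the 4333 macrophage regions had a peak (exact 95% binomial interval of the share 10.0 to 11.9%), 11.1% of the MEF regions (10.5 to 11.7%), 22.4% of the NSC regions (21.6 to 23.2%) and 8.41% of the pre-B regions (7.95 to 8.90%). The mean shares in the other founders' P20 lists were 9.53% for macrophage, 10.9% for MEF, 16.6% for NSC and 13.0% for pre-B regions. The mean excess was 0.700 percentage points, positive in 3 of 4 founders (one-sided exact permutation p = 0.417), and it turned negative without macrophage (-0.311) or pre-B (-0.508). The strongest pre-B region, chromosome 13 at 101610734 to 101614027, lay at percentile 95.6 of its list and had a peak in pre-B P20. The strongest macrophage region, chromosome 4 at 128443528 to 128445227 (90.1), and the strongest MEF region, chromosome 13 at 75981343 to 75982248 (83.3), also had a peak at P20 in their own founder. Of the 2 NSC regions tied as the strongest (80.7), chromosome 18 at 12796722 to 12797681 had a peak in NSC P20 and chromosome 5 at 117042631 to 117043224 did not. Read backwards, P20 founder-specific regions were found at P3 in the same founder more often than in the others for pre-B (by 10.0 points) and NSC (3.82 points). They were found less often for macrophage (-16.7 points) and MEF (-1.06 points). The shortest lists were macrophage at P3 (57032 peaks) and pre-B at P20 (56871). The backward reading was not repeated at equal list lengths, so it does not separate founder from list length.

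CTCF sites overlapped H3K27ac of the same founder and passage in a minority of cases. Of the regions with a CTCF peak in both replicates of a group, the share that overlapped an H3K27ac peak of that group was highest in pre-B P3 (15.0% of 73119 regions, exact 95% binomial interval 14.8 to 15.3%) and lowest in pre-B P20 (10.6% of 57782, 10.4 to 10.9%). The other groups lay between 10.9% in macrophage P20 and 13.8% in NSC P3. The H3K27ac lists covered 61.9 Mb in pre-B P3 and 40.8 Mb in pre-B P20. Over all groups they ran from 39.0 Mb in macrophage P3 (share 11.3%) to 62.0 Mb in NSC P3. A list that covers more bases can overlap more regions by chance. These shares were not repeated at equal list lengths, so they do not separate passage or founder from the extent of the lists. P3 founder-specific CTCF regions overlapped the P3 acetylation of their own founder in 22.6% of cases, averaged over founders, and that of other founders in 17.4%. By founder, another list tied with the own list for macrophage (10% in MEF too), MEF (50% in pre-B too) and pre-B regions (25.1% in NSC too). Only NSC regions overlapped their own list most (5.48%, against at most 4.56% in the others). The difference between the 2 averages, 5.21 points, gave a one-sided exact permutation p of 0.0417, the smallest possible. The largest part came from the 16 MEF regions, of which 9 lay on chromosome X. They overlapped the MEF list in 50% of cases, against 25% for macrophage and 37.5% for NSC. Founders counted equally, so 20 macrophage regions weighed as much as 3706 NSC regions. The difference turned to -0.217 points at equal list lengths (p = 0.75, exact permutation test). It missed the threshold on autosomes alone (2.04 points, p = 0.292, exact permutation test) and with regions built from summits (1.90 points). Left out one at a time, 6 of the 8 P3 CTCF libraries ended the call, all except replicate 2 of NSC and of pre-B, with the lowest value without macrophage P3 replicate 1 (1.51 points).

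Peak strength by chromosome set 4 CTCF libraries apart, in a comparison added after the data were seen. Within each library the 43793 shared CTCF regions were ranked by fold enrichment, and the median deviation of each chromosome from the other libraries, relative to the autosomes, was taken as its offset in percentile points. On chromosome X (1046 regions), replicates 1 and 2 of MEF P3 had offsets of 13.4 and 14.5, the MEF P20 replicates -0.643 and -2.36, and all libraries outside MEF P3 between -4.79 and 1.59. On chromosome 12 (1837 regions), macrophage P3 replicate 2 had an offset of 12.2 and macrophage P20 replicate 1 of 6.44, against -0.411 and -0.148 in the other 2 macrophage libraries and a highest value of 0.353 elsewhere. The change of the chromosome X offset from P3 to P20 in MEF differed from that in the other founders by -17.3 points (two-sided exact permutation of founder labels, p = 0.00638). It did not pass Benjamini-Hochberg adjustment over the 84 founder and measure combinations tested (adjusted p = 0.536, exact permutation), which no single combination could pass alone, since the smallest p that 784 arrangements can give, 0.00128, adjusts to 0.107.

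**Figure D4:**
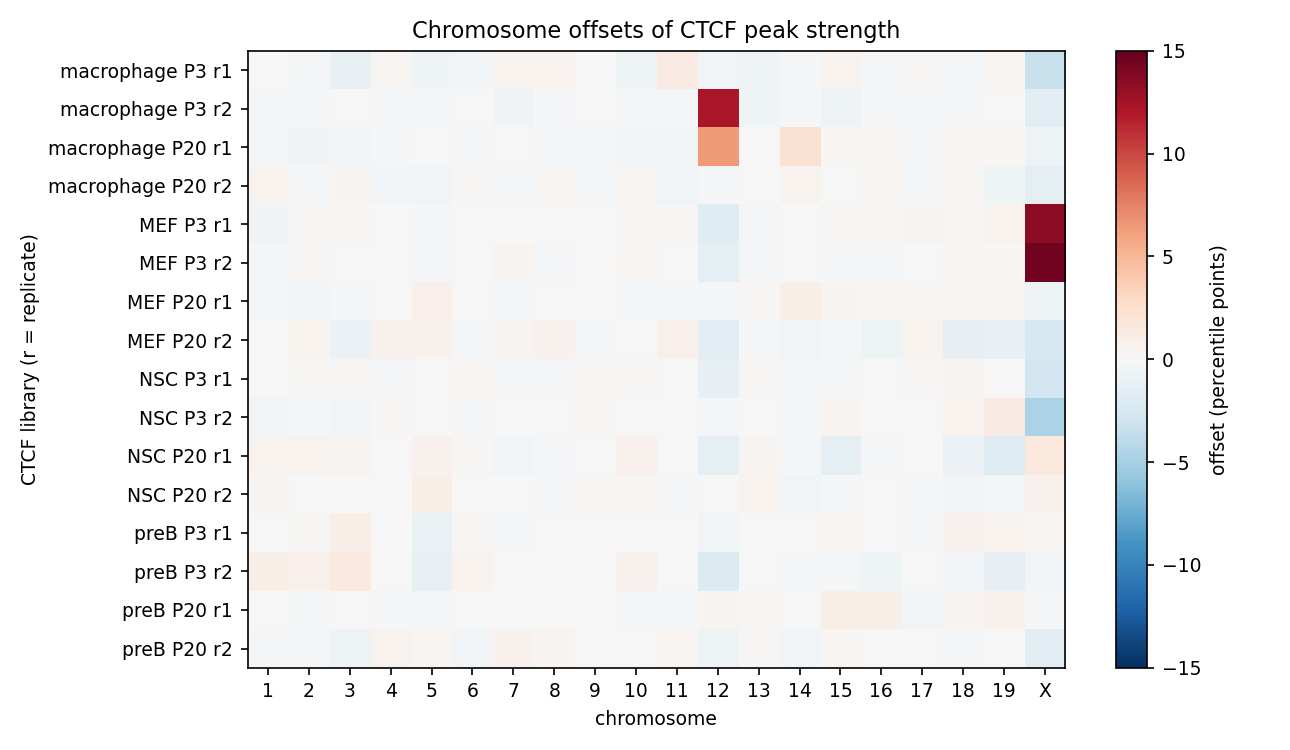
Chromosome offsets of CTCF peak strength, in percentile points, for 16 libraries (vertical axis, by founder) and 20 chromosomes (horizontal axis), over regions that all libraries hold. Chromosome X of both MEF P3 replicates (13.4 and 14.5) and chromosome 12 of macrophage P3 replicate 2 (12.2) and macrophage P20 replicate 1 (6.44) stand out.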

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

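The tests of chromosomes X and 12, of list length for the similarity of lists and of other splits, with their list lengths, and the simulated counts of NSC regions were chosen after the results were seen. The test on the count of NSC regions at equal list lengths was chosen after other results but before that count was made. A library far from the others of its passage was looked for in 100 sets of 4 or 8 libraries, and 9 were found, where chance gives about 1 in 20.

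Chromosome 12 of macrophage P3 replicate 2 (offset 12.2 percentile points) and of macrophage P20 replicate 1 (6.44) lay far above the other 7 CTCF libraries of their passage. All 12 windows of 10 Mb along chromosome 12 lay above 4 points in both libraries (range 4.40 to 17.9), which argues against a few local stretches. The largest offset of another autosome in those libraries was 2.31, on chromosome 14, which argues against a trend over chromosomes such as base composition. A candidate explanation is an extra chromosome 12 in part of these cultures, with the other replicates free of it. The macrophage H3K27ac lists reached 0.803 at most, but the labels do not say which culture they came from, so this hypothesis stays open.

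Chromosome X stood high in both MEF P3 CTCF replicates (mean offset 14.0) and not in MEF P20. A control shared by the P3 lists would raise the other founders too, and their median at P3 was -2.23. All 15 windows of chromosome X were above 5 points in both libraries (range 9.39 to 20.2), which argues against local stretches. The offset was 15.3 at equal list lengths. That cut leaves the fold enrichment of the kept peaks unchanged, and the offset uses only regions that all libraries hold. It could therefore hardly lower the offset and does not decide on list length. Single windows also passed 5 points in P20 lists. MEF P20 replicate 1 lay at 5.18 and 5.20 in the first 2 windows, and NSC P20 replicate 1 reached 7.58 in a later one. A hypothesis that stays open is 2 active X chromosomes in MEF-derived cells at P3 and 1 by P20. The MEF P3 H3K27ac list had the highest chromosome X offset of the 8 (6.17, against 0.779 in MEF P20), although single lists spread nearly as far the other way (-5.87 in macrophage P3, and -2.55 to 2.05 in the rest), and MEF CTCF lists had 0 or 1 peaks on chromosome Y at both passages, against 4 to 24 in other founders. The H3K27ac lists did not share that last feature (6 in both MEF lists, 5 to 22 in the others). Lines of different sex, base composition and a founder effect on the X chromosome in other forms were not tested.

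CTCF lists of one founder resembled one another at P3 and across passages. Cutting the lists to equal lengths left 0.0195 of the P3 difference of 0.0764, still past its threshold, so list length is not its whole source here, although the replicates may share enrichment quality as well as founder. Across passages the difference went from 0.036 to 0.00306 and no longer passed. Regions at an unadjusted p under 0.05 for NSC, 7060 and all more frequent in NSC, went to 733 in both directions, of which 595 were more frequent in NSC (425 of 630 for pre-B and, against the direction with all peaks, 292 of 415 for MEF and 301 of 494 for macrophage). The NSC fall met the criterion that had been set for list length before that count was made. These falls still do not decide between founder and list length, since the cut also takes away the weak peaks among which founder-specific sites lie. The simulated sets with the real list lengths and no founder effect stayed below the observed values at P3 (highest 0.0134), at P20 (0.000556, observed 0.00898), across passages (0.00582) and for NSC regions (2474), but they rest on assumed peak frequencies, so a founder effect and list length both stay open for the across-passage and NSC results, and neither is settled at P20.

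Among other splits of the 16 CTCF libraries, 100 drawn for each comparison, all 101 splits including the real one gave 0 regions after adjustment (highest other 0), which says nothing about chance, since any split gives as many as 0. At an unadjusted p under 0.05, 2 of 101 splits within founder gave as many regions as P3 against P20 (1155, highest other 1339). For NSC, 2 of 101 gave as many (7060, highest other 11385). Such counts were rare among these splits, but NSC and P3 also hold the longer lists. The splits exchanged single libraries, which parts replicates that may be technical, and they were not repeated at equal list lengths. They therefore do not exclude chance for either comparison. For macrophage 19 of 101 gave as many (2103, highest other 11385), for MEF 69 (327, highest other 9060) and for pre-B 31 (1090, highest other 7711), so chance is not excluded. Splits that call several times the real count point to a structure of the samples, which may be list length: over the 400 splits of 4 against 12 libraries, the number of regions rose with the difference in mean list length (Spearman correlation 0.590), and the split with 11385 regions differed by 22799 peaks. Over the 100 splits within founder the Spearman correlation was 0.648, and the split with 1339 regions differed by 12822 peaks. For H3K27ac, 9 of 35 splits gave at least the 296 regions of P3 against P20 (highest other 607), so chance is not excluded.

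The other libraries that stood apart are given as values. Macrophage P3 replicate 1 had the narrowest CTCF peaks of P3 (median 302 bp, others 354 to 384). The same list had offsets of 0.575 on chromosome 8 and 1.19 on chromosome 11. Pre-B P3 replicate 2 had offsets of 0.827 on chromosome 1 and 0.774 on chromosome 2. Macrophage P3 had 57032 H3K27ac peaks, against 76341 to 77373 in the other P3 lists, and NSC P20 had an H3K27ac offset of 0.743 on chromosome 4.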

How the results depend on the processing

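Of 249 recomputed values, 190 kept their direction and side of the threshold or stayed near the main value. That number leaves out 111 CTCF region counts, which stayed at 0 in a test of little reach, 36 values of tests that cannot reach the threshold, and 24 from runs without a library that the result does not use. The runs that left out 3 lists together (macrophage P3 replicate 1, MEF P20 replicate 2 and pre-B P20 replicate 2, the least similar to the rest), the change of founder separation and the chromosome offsets were added after the data were seen. The cause of the changes below was not tested except list length. Depth is unknown, and equal list lengths stand in for it only in part. Such lists give no value for peak numbers, regions from summits do not alter peak numbers, and the H3K27ac counts at gene lists were not run.

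At equal list lengths the same-founder similarity across passages was 0.00306 (p = 0.333, exact permutation test) and the excess overlap of P3 founder-specific CTCF regions with the H3K27ac of their founder was -0.217 points. This overlap was 1.90 points with regions from summits, 2.04 on autosomes, 1.64 without the 3 lists, and 0.334 without them at equal lengths. The excess of P3 founder-specific CTCF regions at P20 passed at −log10 q of at least 10 (15.9 points), with regions from summits (15.8), on autosomes (16.8), when a peak was required in both P20 libraries (5.77) and without the 3 lists (7.63). Without the 3 lists the peak number difference passed (-14390), and the similarity across passages missed the threshold (0.0304, and 0.00467 at equal lengths). The between-founder difference was -0.00205 without them at equal lengths. H3K27ac regions in all lists of one passage and none of the other numbered 121 at −log10 q of at least 10 and 149 with peaks within 1 kb joined. Over all alternatives the mean chromosome X offset of MEF P3 stayed between 12.4 and 16.2, and the chromosome 12 offsets between 10.5 and 14.8 (macrophage P3 replicate 2) and 5.81 and 7.61 (macrophage P20 replicate 1).

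Leaving out 1 CTCF library at a time gave differences of -10488 to -3496 for peak number, 0.058 to 0.101 for founder separation at P3, -0.0273 to 0.0491 at P20, -0.104 to -0.0273 for its change, 0.0128 to 0.0539 for similarity between founders, and 0.0215 to 0.0506 for similarity across passages. The excess at P20 ran from 4.63 to 16.9 points, lowest without NSC P3 replicate 2, and passed without either MEF P3 replicate (10.8 and 12.8) or pre-B P20 replicate 2. The overlap with H3K27ac ran from 1.51 to 7.60 points, with founders left out as well, lowest without macrophage P3 replicate 1. The separation at P20 turned negative without either NSC P20 replicate, and its change passed without either of them, macrophage P3 replicate 2 or macrophage P20 replicate 1. Leaving out 1 founder at a time, which cannot reach the threshold, gave H3K27ac differences of -9677 to 913 peaks, -9.41 to 0.773 Mb, -0.0123 to 0.0362 between founders, -0.00414 to 0.00507 across passages and -0.508 to 2.28 points for founder-specific regions. The H3K27ac regions that parted the passages then numbered 881 to 2175, since fewer libraries had to match. CTCF region counts stayed at 0 in all runs.

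Replicate numbers did not pair the samples: the presence differences between replicates 1 and 2 correlated at -0.216 to 0.233 over 28 pairs of groups, above 0.1 in 4. With the replicate block the peak number difference was -7777 (p = 0.203, exact permutation test), the between-founder difference 0.0392 (p = 0.383) and the region count 0 (exact sign test, 247 at an unadjusted p under 0.05), so no call changed.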

Other observations

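The H3K27ac regions that part P3 from P20 in 3 founders were read in the founder left out, a test chosen after the data were seen. At equal list lengths, the 424 regions found in P3 of macrophage, MEF and NSC and in none of their P20 lists had a peak in 53.8% of cases in pre-B P3 and in 19.3% in pre-B P20 (exact 95% binomial intervals 48.9 to 58.6% and 15.7 to 23.4%). For NSC the shares were 56.9% at P3 and 27.5% at P20 (432 regions), and for MEF 54.5% and 35.1% (510 regions). Macrophage went the other way, with 35.1% at P3 (32.1 to 38.1%) and 51.1% at P20 (47.9 to 54.3%) of 984 regions. Regions found in P20 alone of the 3 other founders were more frequent at P20 than at P3 in MEF (57.3% and 37.5% of 232), at equal shares in NSC (58.4% of 409), and within each other's intervals in pre-B (43.6% and 41.2% of 374) and macrophage (23.2% and 24.9% of 583). With all peaks the regions of P20 alone went apart in both, less frequent at P20 than at P3 in pre-B (28.2% and 39.4% of 472) and more frequent in macrophage (21.9% and 10.9% of 366), so their direction depends on whether the lists have equal lengths. The intervals cover counting error only, with 1 library per group. The control behind each list is not given. A control shared by the lists of one passage could also make regions recur in the founder left out, and this was not set apart from passage. The split of the 8 lists with the most regions, 607, differed from the real one by exchanging the macrophage lists.

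Some windows of 100 kb held many founder-specific H3K27ac regions at P3. They are given as values, since no comparison was made with the density of all H3K27ac regions, and broad domains split into several peaks could not be set apart. In pre-B P3, 35 regions absent from the other P3 lists lay between 77707855 and 77798869 on chromosome 2, and 15 of them had a peak in pre-B P20. The next 20 lay between 77800792 and 77859469, with 4 found in pre-B P20. In MEF P3, 18 such regions lay between 130205390 and 130291125 on chromosome 4, none of them in MEF P20, and 14 between 70925372 and 70992222 on chromosome X, with 1 in MEF P20. In NSC P3, 11 lay between 79202475 and 79287490 on chromosome 15, with 7 in NSC P20. Chromosome X held 5.19% of the MEF P3-specific H3K27ac regions, against 0.577% for macrophage, 0.977% for NSC and 2.07% for pre-B. Among all peaks of the P3 lists the contrast was smaller. Chromosome X held 2398 of 76415 peaks in MEF, 1349 of 57032 in macrophage, 1883 of 77373 in NSC and 2099 of 76341 in pre-B. Since specific regions are absent from the other P3 lists, more peaks on chromosome X in one list lower the shares of the others.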
